A study of Mus musculus with 22 samples.

How the data were processed

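RNA from renal capsules, the thin fibrous sheath around the kidney, and from macrophages was sequenced in bulk in 22 mouse libraries, which the sample titles place in 6 groups. Capsule tissue of young and of aged mice gave 3 libraries each. Macrophages of the capsule, macrophages of the kidney, young RCAM libraries and aged RCAM libraries gave 4 each. The labels do not expand RCAM. They list the cell type of the RCAM libraries as whole tissue, while the series text describes capsules sorted by flow cytometry for macrophages, so the labels alone left the identity of these libraries open. The labels give no ages, sexes or batches, and no age for the capsule and kidney macrophages. Nothing states that replicates of a group were separate animals, so p-values measure only the spread between these samples, which may be technical.

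Per the labels, a regular-input stranded mRNA kit with 100 ng of total RNA and a low-input kit with 2 ng were both used, without saying which sample had which. The labels state 30 M (1e6) single-end reads of 50 bp per sample. The files deposited by the authors hold whole-number counts of reads per gene for 52636 genes, not normalized. They also hold RPKM values computed by the authors with a gene width that equalled the genomic span of the gene for 85.6% of genes and with a read total 5.17 to 12.11% above the sum of the counts. The RPKM values were not used. The submitters' processing notes name GRCm38, while the aligner and counter, and whether counting used strand, are not given in the sources used here. Gene symbols and coordinates came from the GENCODE M21 annotation of GRCm38, in which 52489 of the gene identifiers were found and 147 were not. Without stated use of strand, reads of a gene and of an overlapping antisense gene cannot be told apart, and reads of 50 bp can be split between near-identical genes.

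Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, 2-sided, after TMM scaling and the default expression filter, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A fit held only the groups compared. Each printed level of a gene is in counts per 1e6 (CPM) of the TMM-scaled library total over the genes that passed the filter. Each list sum is in CPM of the unscaled library total over all genes. Both are printed as mean ± SD over the libraries of a group, and each error of a log2 fold change is its standard error. There were 3 comparisons, namely aged against young capsule tissue, capsule against kidney macrophages, and aged against young RCAM libraries. An interaction test asked whether the age effect differed between RCAM libraries and capsule tissue, and Pearson's r compared the 2 age effects across genes, which are not independent replicates. The 200 genes of largest fold change towards the capsule and the 200 towards the kidney in the macrophage comparison, with a mean log2 CPM of at least 3, were tested as sets in both age comparisons.

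Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, inter-gene correlation preset at 0.01), adjusted over the lists with at least 5 measured members. Of 58 lists, 1506 members were found in the files and 4 were not. With the correlation estimated per list, no list was called in capsule tissue, 1 in the macrophage comparison and 3 in RCAM libraries; each p with an estimated correlation is printed beside its list. Summed CPM of a list was compared by an exact permutation test, 2-sided, which cannot go below 0.1 with 3 libraries against 3, or below 0.0286 with 4 against 4.

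The grouping, the tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule took, in each comparison, the 8 genes with the largest positive and the 8 with the largest negative log2 fold change among genes past the threshold with a mean log2 CPM of at least 3, a named symbol and no overlap between the groups. It added up to 4 members of smallest p of each list described, and Csf1r, Adgre1, Lyve1, Cx3cr1, Slc34a1, Col1a1, Acta2 and Pecam1. Which lists to describe, and which of the genes taken by the rule to print, was decided after their values were seen.

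Titles number the replicates 1 to 3 or 1 to 4 in each group without saying that a number marks a shared animal or day. In capsule tissue the deviations from the group means correlated between young and aged libraries of the same number at r = 0.213, 0.543 and 0.508. Libraries of unequal number gave -0.5 to 0.105. The numbers were taken to pair the samples there, from this correlation and not from the labels. Deviations cancel within a group, so these r values are not independent. Replicate 2 of both groups, with r = 0.543, also held the adrenal transcripts, so the correlation cannot show a shared animal or day. The pairing was thus chosen from the same expression values that the block fit then tested. Calls and p-values with the block hold only if the pairing is real. The fit with the replicate number as a block is printed beside a capsule result where it changed the call or moved a count of calls by over 1.5 times. Other alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, no filter and a stricter filter (CPM of at least 5), all 22 libraries in 1 fit, other thresholds, removal of immunoglobulin, mitochondrial and haemoglobin genes before scaling and test, the proximal tubule list as a covariate, the rotation test fry, and each library left out in turn. After the data were seen, both capsule libraries with adrenal transcripts and both aged RCAM libraries with most fibroblast transcripts were also left out, and the immunoglobulin, mitochondrial and haemoglobin genes were left out of the scaling alone. The site sets were then also tested without members of the fibroblast and matrix lists, and list sums in capsules within pairs.

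Total counts ran from 20.6 to 54.4 M per library. No pair of libraries of the same group agreed within sampling noise, so none was merged. For a gene at 0 counts in a group, fold changes are bounds computed against 3 counts over that group, and for 1 to 3 counts the ratio has a 95% counting interval; both cover counting error only. The tests were tried on simulated counts with 200 changed genes. edgeR recovered 12% of genes changed 2-fold and 81% of those changed 4-fold in the capsule design (16054 genes), with unchanged genes making up 14.7% of its calls. It recovered 59% and 87% in the macrophage design (15363 genes, 2% unchanged among the calls), 61% and 97% in the RCAM design (14846 genes, 6%) and 16% and 61% for the interaction (18856 genes, 3.8%). In the same simulations unchanged genes were 28.8%, 20.1% and 18.8% of the DESeq2 calls for the 3 comparisons, and 11.9%, 1.4% and 6% of the limma-voom calls.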

Results

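Gene expression was measured by bulk RNA sequencing in mouse renal capsule tissue (young and aged, n = 3 libraries each), in macrophages taken from the renal capsule and from the kidney (n = 4 each), and in libraries named RCAM (young and aged, n = 4 each). Total counts per library, in M (1e6), were 20.6 to 22.2 in young capsules, 27.1 to 43.2 in aged capsules, 39.3 to 53.4 in capsule macrophages, 31.8 to 49.9 in kidney macrophages, 49.8 to 54.4 in young RCAM libraries and 45.0 to 51.8 in aged RCAM libraries. The labels do not spell out RCAM and give these libraries as whole tissue, while the series text speaks of sorted macrophages. The labels thus leave the cells uncertain. Pan-macrophage genes summed to 41530 to 46360 CPM in RCAM libraries, 40660 to 44250 CPM in capsule macrophages and 2298 to 11430 CPM in capsule tissue. Adipocyte genes summed to 277 to 438 CPM in RCAM libraries and 31890 to 79800 CPM in capsule tissue. These sums argue against whole capsule tissue in the RCAM libraries.

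The first comparison asked how capsule tissue of aged mice differed from that of young mice. Transcripts of antibody-producing cells were higher in aged capsules. Ighm, the constant region of the immunoglobulin M heavy chain (ENSMUSG00000076617, GRCm38 chromosome 12, 113418558 to 113422730), rose from 166 ± 22.6 to 3681 ± 803 CPM (SD, n = 3), a log2 fold change of 4.47 ± 0.31 (edgeR adjusted p = 0.00918). Jchain, which joins immunoglobulin units into polymers (ENSMUSG00000067149, chromosome 5, 88519809 to 88527891), rose from 6.30 ± 3.43 to 414 ± 246 CPM (log2 fold change 6.04 ± 0.64, adjusted p = 0.0249, 5.43 without aged replicate 3). Fabp3, a fatty acid carrier of oxidative tissue (ENSMUSG00000028773, chromosome 4, 130308595 to 130315463), fell from 10.9 ± 3.20 to 0.818 ± 0.228 CPM (log2 fold change -3.75 ± 0.37, adjusted p = 0.0229). Acss1, a mitochondrial acetyl-CoA synthetase, fell from 152 ± 31.8 to 44.4 ± 5.96 CPM (log2 fold change -1.78 ± 0.21, adjusted p = 0.0308). Of 16350 genes tested, 25 were higher and 14 lower in aged capsules, 0.2% of all, while 3685 had an unadjusted p under 0.05. With the replicate number as a block, 943 genes were higher and 1253 lower, including all 39 called without it. DESeq2 called 754 higher and 1122 lower, and limma-voom 580 and 953. Of the 25 higher genes, 14 were immunoglobulin genes. Removing immunoglobulin, mitochondrial and haemoglobin genes from both scaling and test left 4 higher and 4 lower of the other 11 and 14. With these genes out of the scaling alone and all genes tested, 29 were higher and 22 lower, including all 39, and the share of higher genes went from 64.1% to 56.9%. That scaling was chosen after the data were seen. In edgeR without young replicate 1 or without aged replicate 1 the count was 0, with 2828 and 2352 genes at an unadjusted p under 0.05, and Ighm then had an adjusted p of 0.0847 and 0.0936. The counts were 63 higher and 324 lower without young replicate 2, 5 and 1 without young replicate 3, 93 and 22 without aged replicate 2, and 14 and 9 without aged replicate 3. Jchain and Acss1 missed the threshold without young replicate 3 (0.051 and 0.054), as did Acss1 without aged replicate 3 (0.0607). Groups did not overlap for 4407 genes, 27% of those tested, where chance gives 10%. Transcripts of the adrenal list summed to 218 CPM in young replicate 2 and 6884 CPM in aged replicate 2, against 25 CPM or less in the other capsule libraries, and without both libraries 176 genes were higher and 311 lower.

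B-lineage lists were higher in aged capsules. Of 80 measured immunoglobulin gene segments, 14 rose and none fell (73 rose adjusted over the list alone, 67 with the replicate block). Their median log2 fold change was 5.90, or 5.54 with the 15 segments at 0 counts in 1 group set to their bound. The list held 261 segments, and the number past the filter changed when a library was left out. The median was 6.64, 6.70 and 7.02 over 120 segments each without young replicate 1, 2 or 3. Without aged replicate 1, 2 or 3 it was 6.08, 5.48 and 6.02 over 87, 77 and 100 segments. The whole list, with segments too low to test, summed to 195 ± 40.7 CPM in young and 5292 ± 1220 CPM in aged capsules (exact permutation p = 0.1, the smallest possible). The list was higher as a set (camera adjusted p = 1.1e-48, adjusted p = 0.181 with an estimated correlation). Segments are near-identical in places, so the split of counts among them is uncertain. Whether reads were shared by the light chain constant genes Iglc1 (0.750 to 44.0 CPM) and Iglc2 (0.847 to 23.6 CPM) was not tested. Iglc2 had a log2 fold change of 4.78, or 6.08 without young replicate 3. Of 16 B cell genes, Cd22, an inhibitory co-receptor, and Cd79a, a signalling chain of the B cell receptor, rose with log2 fold changes of 3.43 ± 0.42 and 1.84 ± 0.25 (adjusted p = 0.0339 and 0.0447). Adjusted over the list alone 13 of them rose, and 11 with the block (camera adjusted p = 1.97e-10, adjusted p = 0.541 with an estimated correlation). Of 14 plasma cell genes, 3 rose, namely Jchain, the chaperone Mzb1 (log2 fold change 3.71 ± 0.53, adjusted p = 0.0469, 4.32 without young replicate 3) and the B cell coactivator Pou2af1 (3.08 ± 0.36, adjusted p = 0.028). Adjusted over the list alone, as with the block, 5 plasma cell genes rose and 1 fell (camera adjusted p = 0.00331, adjusted p = 0.541 with an estimated correlation, and 0.0813 with the preset one without aged replicate 3). Without young replicate 1 or aged replicate 1 none of these genes passed. The segments past the threshold numbered 24 without young replicate 2, 5 without young replicate 3, 22 without aged replicate 2 and 10 without aged replicate 3. No B cell gene passed without young replicate 3 or aged replicate 3, and 0 and 1 plasma cell genes did.

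T cell transcripts stood higher as a group without any single gene reaching the threshold over all genes. Of 26 T cell genes, 0 passed in edgeR, against 20 adjusted over the list alone, 18 with the replicate block, 21 at an unadjusted p under 0.05, 17 by limma-voom and 18 by DESeq2. Their median log2 fold change was 1.43 (camera adjusted p = 1.12e-16, adjusted p = 0.402 with an estimated correlation). Cd8b1, a co-receptor chain of cytotoxic T cells, and Cd3e, a T cell receptor subunit, had log2 fold changes of 2.38 ± 0.35 and 1.77 ± 0.28 (adjusted p = 0.0505 and 0.0555, and 0.004 and 0.0105 with the block). Of 16 NK and cytotoxic lymphocyte genes, 0 passed, 8 did adjusted over the list alone, 4 with the block, 8 unadjusted, 4 by limma-voom and 5 by DESeq2 (camera adjusted p = 4.19e-06, adjusted p = 0.541 with an estimated correlation). Nkg7, a granule protein of killer cells, had a log2 fold change of 1.62 ± 0.38 (adjusted p = 0.0894, 0.0224 with the block). Of 8 lymphoid chemokine genes, 0 passed, 3 did adjusted over the list alone, 3 with the block, 4 unadjusted, 3 by limma-voom and 3 by DESeq2 (camera adjusted p = 0.0019, adjusted p = 0.541 with an estimated correlation). Cxcl13, the B cell attractant, stood at 12.6 ± 1.47 CPM in young and 65.9 ± 49.8 CPM in aged capsules (adjusted p = 0.0875, 0.0307 with the block). Its log2 fold change was 2.38, or 1.63 without aged replicate 2. Without young replicate 2, 5 T cell genes and 1 cytotoxic gene passed, Cd8b1 (0.0396) and Cd3e (0.0462) among them, and without aged replicate 2, 2 T cell genes passed, Cd8b1 (0.0326) among them.

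**Figure D1:**
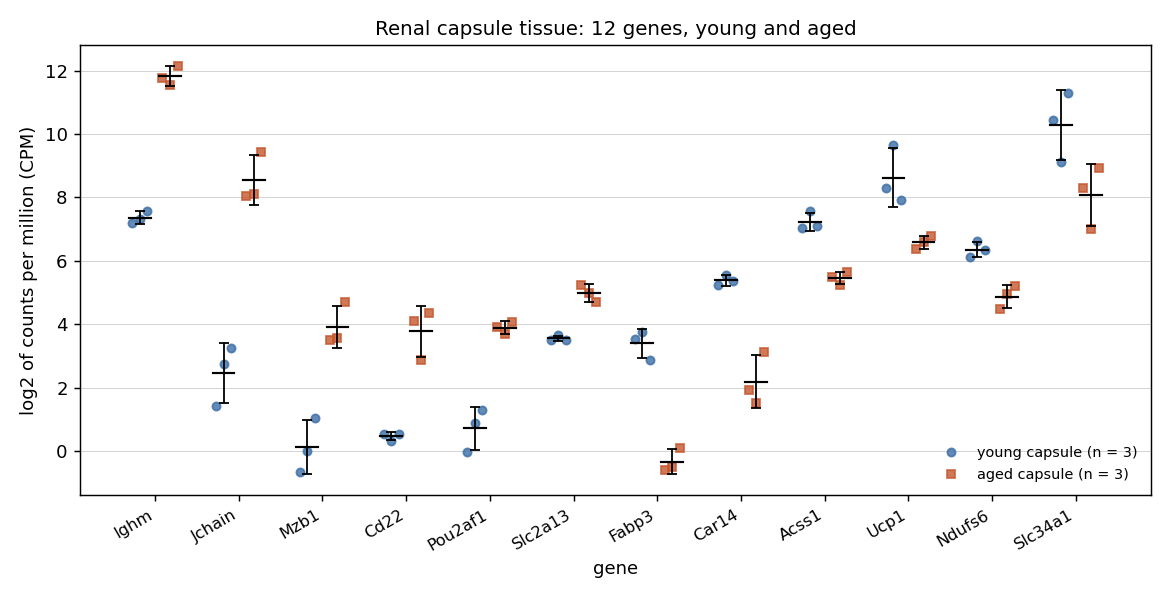
Level of 12 genes in young and aged capsule libraries, as log2 CPM, with a point per library and a black bar at the mean ± SD of the log2 values. Ighm stood at 166 CPM in young and 3681 CPM in aged capsules, and Acss1 at 152 and 44.4 CPM, without overlap between the groups.

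Further immune lists were described. For MHC class I presentation (14 genes, median log2 fold change 0.51), complement (20, 0.74), inflammatory cytokines and NF-kB (19, 0.56) and interferon-stimulated genes (34, 0.46), 0 members passed in edgeR. Adjusted over the list alone 6, 7, 9 and 0 members passed, and with the replicate block 5, 10, 7 and 7. There were 7, 10, 9 and 13 at an unadjusted p under 0.05, by limma-voom 4, 6, 3 and 3, and by DESeq2 7, 7, 6 and 6, all higher in aged capsules. All 4 lists were higher as sets (camera adjusted p = 3.34e-05, 7.82e-06, 2.48e-05 and 6.34e-06, adjusted p = 0.541, 0.541, 0.541 and 0.622 with an estimated correlation). C4b, complement component 4, stood at 335 ± 73.1 CPM in young and 888 ± 186 CPM in aged capsules (adjusted p = 0.0711, 0.00679 with the block). Tnfaip3, an inhibitor of NF-kB, had a log2 fold change of 1.22 ± 0.21 (0.0636, 0.00638 with the block) and the chemokine Ccl5 one of 1.89 ± 0.34 (0.0666, 0.012 with the block). H2-Q6 and H2-Q4, class I genes of a family with near-identical members, had 1.38 ± 0.22 and 0.96 ± 0.19 (0.0591 and 0.0723, 0.00211 and 0.00894 with the block). Without young replicate 2, H2-Q6 (0.041) and Ccl5 (0.0444) passed, as did H2-Q6 without aged replicate 2 (0.0441). Each of the class I, complement and inflammatory lists had 1 member past the threshold without either library, and the interferon list had none. Of 15 pan-macrophage genes, 0 passed, 3 did adjusted over the list alone, 11 with the block, 8 unadjusted, 1 by limma-voom and 4 by DESeq2 (median 0.90, camera adjusted p = 9.79e-05, adjusted p = 0.632 with an estimated correlation). Among them were Cd68, a lysosomal glycoprotein (log2 fold change 1.83 ± 0.50, or 1.24 without aged replicate 3, adjusted p = 0.106, 0.0102 with the block, 0.0423 without aged replicate 2), and the macrophage surface genes Adgre1 (1.16 ± 0.43, 0.166, 0.0111 with the block) and Csf1r (0.64 ± 0.27, 0.214). Lyve1 (0.32 ± 0.30, 0.567), Cx3cr1 (-0.16 ± 0.31, 0.799, but 0.18 without young replicate 3), the muscle actin Acta2 (0.83 ± 0.42, 0.289) and the endothelial gene Pecam1 (0.48 ± 0.27, 0.337) did not pass with or without the block. Fibrillar collagen and interstitial matrix genes showed no shift as a set (36 genes, median 0.03 and mean 0.05 with camera pointing downward, adjusted p = 0.904, adjusted p = 0.984 with an estimated correlation). None of them passed in edgeR or adjusted over the list alone, 2 were lower at an unadjusted p under 0.05, 2 were lower by limma-voom, 1 was lower by DESeq2, and 1 was higher with the block. Col3a1 (-0.72 ± 0.24, 0.143) and Col1a1 (-0.66 ± 0.26, 0.19) did not pass.

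Mitochondrial genes were lower in aged capsules as a group. Of 80 nuclear-encoded genes of oxidative phosphorylation, 0 passed in edgeR, whereas 67 were lower adjusted over the list alone, 63 with the replicate block, 68 at an unadjusted p under 0.05, 46 by limma-voom and 59 by DESeq2. Their median log2 fold change was -1.09 (camera adjusted p = 3.61e-25, adjusted p = 0.541 with an estimated correlation). Their summed level was 25290 ± 7930 CPM in young and 12620 ± 2580 CPM in aged capsules (exact permutation p = 0.1, the smallest possible). Ndufs6, a subunit of respiratory complex I, had a log2 fold change of -1.47 ± 0.23 (adjusted p = 0.0555, 0.00237 with the block, 0.0396 without young replicate 2). Of 11 mitochondrially encoded genes, for which reads of nuclear copies cannot be excluded, 0 passed, 11 were lower adjusted over the list alone, 9 with the block, 11 unadjusted, 5 by limma-voom and 10 by DESeq2 (median -1.37, camera adjusted p = 4.96e-09, adjusted p = 0.541 with an estimated correlation). The oxidase subunit gene mt-Co1 stood at 5153 ± 1720 CPM in young and 2046 ± 114 CPM in aged capsules (0.0907, 0.024 with the block). Markers of brown and beige fat and of kidney tubules were lower in the same libraries. Of 13 brown and beige adipocyte genes, Fabp3 fell (8 were lower adjusted over the list alone, and 6 lower and 1 higher with the block; camera adjusted p = 6.96e-05, adjusted p = 0.622 with an estimated correlation). Ucp1, the uncoupling protein of thermogenic fat, stood at 456 ± 312 and 96.6 ± 13.8 CPM (0.0768, 0.0135 with the block, 0.0357 without young replicate 2). Its log2 fold change was -2.24, or -1.55 without young replicate 2. The muscle and brown fat isoforms Cox8b and Cox7a1 had log2 fold changes of -2.77 ± 0.47 and -3.22 ± 0.56 (0.0627 and 0.0643, 0.00541 and 0.012 with the block, 0.0354 and 0.037 without young replicate 2, where the fold changes were -2.19 and -2.59). The brown fat list summed to 2617 ± 1700 CPM in young and 846 ± 369 CPM in aged capsules (exact permutation p = 0.2). Young replicates 1 to 3 had 2176, 4493 and 1181 CPM. The median log2 fold change of the list was -2.24, or -1.47 without young replicate 2. The general adipocyte list stood at 50020 ± 22200 and 55530 ± 21000 CPM (exact permutation p = 0.6). Without young replicate 2, 3 oxidative phosphorylation, 2 mitochondrially encoded and 4 brown fat genes passed. Without young replicate 1 or aged replicate 1 none did.

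Kidney tubule transcripts were lower as well. Of 30 proximal tubule genes, 0 passed in edgeR, 26 were lower adjusted over the list alone, 28 with the replicate block, 26 unadjusted, 25 by limma-voom and 24 by DESeq2. Their median log2 fold change was -2.09, or -2.79 without aged replicate 3 (camera adjusted p = 9.79e-13, adjusted p = 0.541 with an estimated correlation). Their sum was 29850 ± 12000 CPM in young and 9987 ± 3340 CPM in aged capsules (exact permutation p = 0.1). Slc34a1, the phosphate transporter of the proximal tubule, stood at 1490 ± 982 and 311 ± 182 CPM (adjusted p = 0.11, 0.0013 with the block), a log2 fold change of -2.26, or -1.64 without young replicate 3. The fatty acid transporter Slc27a2 and the endocytic receptor Lrp2 had log2 fold changes of -2.30 ± 0.57 and -2.33 ± 0.59 (0.0929 and 0.0971, 0.00198 and 0.00193 with the block, 0.0438 and 0.0357 without young replicate 2). Without aged replicate 3 Slc27a2 had -2.99. Of 19 loop and distal nephron genes, 0 passed, 14 were lower adjusted over the list alone, 15 with the block, 14 unadjusted, 13 by limma-voom and 12 by DESeq2 (median -1.87, or -2.46 without aged replicate 3, camera adjusted p = 9.91e-09, adjusted p = 0.541 with an estimated correlation). Among them was the growth factor gene Egf (-2.30 ± 0.49, 0.0826, 0.00245 with the block, 0.0322 without young replicate 2). Without young replicate 2, 10 proximal tubule and 6 loop genes passed. Of 9 erythroid genes, 0 passed, 8 were lower adjusted over the list alone, 8 with the block, 8 unadjusted, 1 by limma-voom and 8 by DESeq2 (median -1.58, or -0.91 without young replicate 3, camera adjusted p = 0.000149, adjusted p = 0.622 with an estimated correlation). They included Alas2, the first enzyme of haem synthesis in red cells (-1.55 ± 0.52, 0.142, 0.00377 with the block, -0.88 without young replicate 3). Erythroid transcripts summed to 15460 ± 10200 CPM in young and 5581 ± 3270 CPM in aged capsules (exact permutation p = 0.2). Within the 3 pairs of equal replicate number, the aged sum was 0.435, 0.350 and 0.346 times the young one for the erythroid list and 0.274, 0.283 and 0.569 times for the brown fat list. For the adipocyte list it was 1.02, 1.07 and 1.33 times. Each gave an exact permutation p of 0.25 within pairs, the smallest possible, in a test added after the data were seen. Outside these lists the carbonic anhydrase Car14 fell from 42.2 ± 5.07 to 5.14 ± 3.10 CPM (adjusted p = 0.0447), a log2 fold change of -3.05, or -3.64 without aged replicate 3. Ces1g, a carboxylesterase with near-identical relatives (-3.09), Itih4 (-2.52), Itm2a (-2.34), Akr1c18 (-1.89), the nuclear receptor Esrrg (-1.56) and Pm20d1 (-1.54) also fell (adjusted p = 0.0322 to 0.0462). The inositol transporter Slc2a13 rose from 11.8 ± 0.709 to 32.0 ± 6.11 CPM (0.045). None of these passed without young replicate 1 or aged replicate 1 or, at 0.054 to 0.0979, without young replicate 3. Without aged replicate 3, Ces1g, Itih4, Akr1c18 and Esrrg (0.0664 each) and Pm20d1 and Slc2a13 (0.0508 each) missed it, as did Pm20d1 (0.0589) and Slc2a13 (0.0505) without aged replicate 2. Without both adrenal libraries, 32 immunoglobulin segments and 3 B cell, 4 T cell, 1 cytotoxic, 2 class I, 4 complement, 3 inflammatory, 1 interferon and 1 pan-macrophage genes were higher. There were then 17 proximal tubule, 7 loop, 4 brown fat and 2 oxidative phosphorylation genes lower, and the brown fat median went from -2.24 to -1.31.

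**Figure D2:**
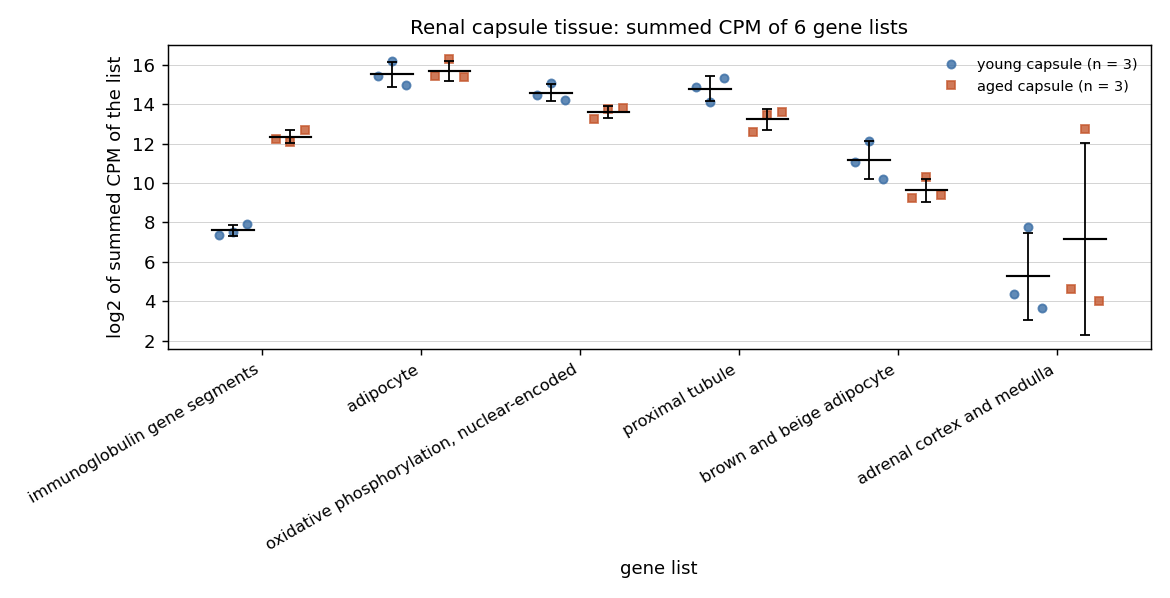
Summed CPM of 6 gene lists per capsule library, on a log2 axis, with a point per library and a black bar at the mean ± SD of the log2 values. The immunoglobulin sum was 195 CPM in young and 5292 CPM in aged capsules, the proximal tubule sum 29850 and 9987 CPM, and the adrenal sum stood apart in replicate 2 of both groups.

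The second comparison set macrophages of the capsule against macrophages of the kidney. Genes of the Lyve1-type resident macrophage list were higher in capsule macrophages. Lyve1, a hyaluronan receptor (ENSMUSG00000030787, chromosome 7, 110850607 to 110863239), stood at 1.33 ± 0.518 CPM in kidney and 1285 ± 239 CPM in capsule macrophages (n = 4 each, log2 fold change 9.91 ± 0.29, edgeR adjusted p = 2.99e-09). The folate receptor Folr2 (ENSMUSG00000032725, chromosome 7, 101839988 to 101857194) stood at 4.11 ± 0.708 and 1749 ± 91.1 CPM (8.74 ± 0.15, adjusted p = 1.15e-10). All 23 measured genes of the Lyve1-type resident macrophage list were higher in the capsule (23 adjusted over the list alone, camera adjusted p = 3.62e-18, adjusted p = 0.0341 with an estimated correlation). Their sum was 2103 ± 85.4 CPM in kidney and 33240 ± 2070 CPM in capsule macrophages (exact permutation p = 0.0286, the smallest possible). Among them were Retnla, a marker of alternative activation (30.9 ± 6.13 and 12070 ± 879 CPM), the haemoglobin scavenger receptor Cd163 (27.6 ± 3.17 and 1457 ± 177 CPM) and the phosphatidylserine receptor Timd4 (1.28 ± 0.480 and 371 ± 45.5 CPM). They also included the carbonyl reductase Cbr2 (log2 fold change 8.92 ± 0.15) and the lectin Cd209f (9.78 ± 0.19), whose reads may be shared with other Cd209 genes. Of 15701 genes tested, 4281 were higher and 4420 lower in capsule macrophages, 55.4% of all, and 1885 and 2443 changed at least 2-fold. Groups did not overlap for 53.2% of genes, where chance gives 2.86%.

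Most genes of the Cx3cr1-type kidney macrophage list were higher in kidney macrophages, while the summed level of the list was higher in the capsule (19010 ± 1260 and 24470 ± 1940 CPM, exact permutation p = 0.0286). Of 14 measured, 10 were lower and 3 higher in the capsule (10 and 3 adjusted over the list alone, camera adjusted p = 0.0426, adjusted p = 0.572 with an estimated correlation). With the preset correlation the adjusted p was 0.0548 without capsule replicate 3 and 0.0596 without kidney replicate 4. The fractalkine receptor Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879) stood at 1107 ± 64.6 CPM in kidney and 353 ± 72.0 CPM in capsule macrophages (log2 fold change -1.65 ± 0.14, adjusted p = 3.64e-06). The inhibitory receptor Cd72 stood at 1181 ± 46.5 and 76.8 ± 13.5 CPM (-3.94 ± 0.13) and the integrin Itgax at 313 ± 14.6 and 53.3 ± 7.64 CPM (-2.56 ± 0.11). Of 11 MHC class II presentation genes, 8 were lower and 1 higher (8 and 1 adjusted over the list alone, camera adjusted p = 0.0297, adjusted p = 0.654 with an estimated correlation). These included the invariant chain Cd74 (67570 ± 6750 and 41190 ± 4800 CPM) and H2-Eb1 (-0.91 ± 0.14). Pan-macrophage genes were present at high levels on both sides, summing to 33030 ± 1390 and 42490 ± 1890 CPM (exact permutation p = 0.0286). Of 16 measured, 13 were higher and 1 lower in the capsule (13 and 2 adjusted over the list alone, camera adjusted p = 0.00792, adjusted p = 0.572 with an estimated correlation). Csf1r stood at 4043 ± 296 and 7705 ± 607 CPM (adjusted p = 4.42e-06) and Adgre1 at 1547 ± 61.5 and 1821 ± 50.3 CPM (0.0068, lost with all 22 libraries in 1 fit at 0.424).

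**Figure D3:**
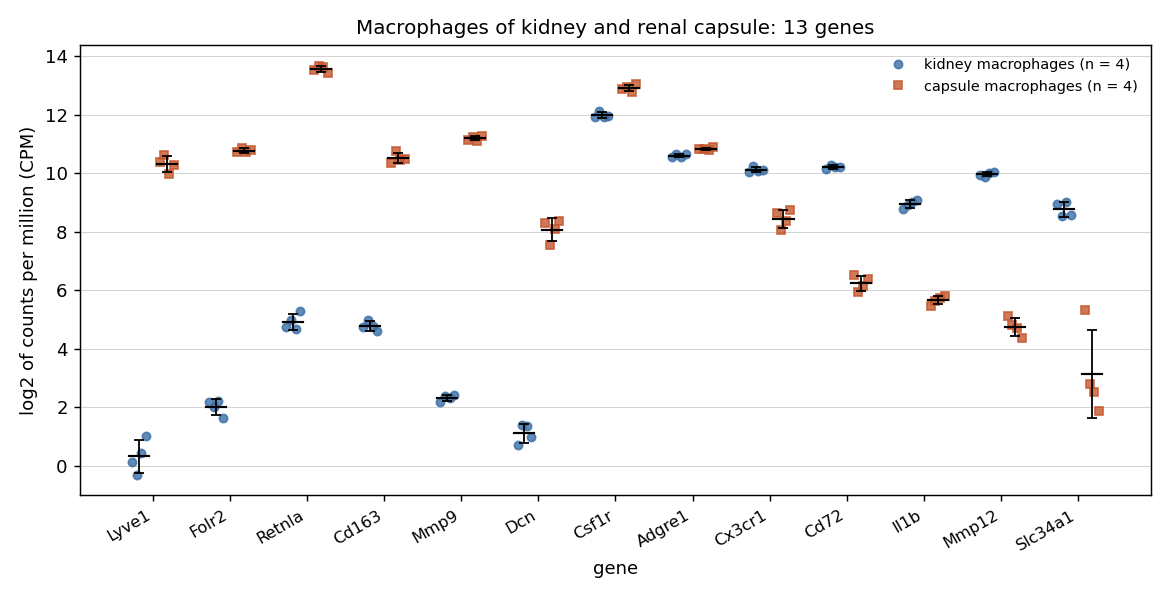
Level of 13 genes in kidney and capsule macrophage libraries, as log2 CPM, with a point per library and a black bar at the mean ± SD of the log2 values. Lyve1 stood at 1.33 CPM in kidney and 1285 CPM in capsule macrophages and Cd72 at 1181 and 76.8 CPM, and the tubule gene Slc34a1 was 40.3 CPM in capsule replicate 1 and 3.71 to 6.93 CPM in the other capsule libraries.

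Effector genes also parted by site. Of 21 complement genes, 20 were higher in the capsule (20 adjusted over the list alone, camera adjusted p = 1.24e-09, adjusted p = 0.0831 with an estimated correlation). Properdin (Cfp) stood at 120 ± 15.6 CPM in kidney and 3018 ± 352 CPM in capsule macrophages, C3 at 38.3 ± 5.23 and 331 ± 28.3 CPM, and C6 had a log2 fold change of 9.71 ± 0.42, or 10.51 without kidney replicate 3. Scavenger and efferocytosis receptors were higher for 13 and lower for 4 of 18 genes (13 and 4 adjusted over the list alone, camera adjusted p = 0.000502, adjusted p = 0.52 with an estimated correlation). Of 17 genes of alternative activation, 11 were higher and 3 lower (11 and 3 adjusted over the list alone, 0.0157, adjusted p = 0.572 with an estimated correlation). Lipid-associated macrophage genes were higher for 14 and lower for 4 of 19 (14 and 4 adjusted over the list alone, 0.0105, adjusted p = 0.251 with an estimated correlation). Lysosome genes were higher for 18 and lower for 4 of 30 (18 and 5 adjusted over the list alone, 0.00228, adjusted p = 0.572 with an estimated correlation), with the protease Ctsd at 81.3 ± 6.13 and 572 ± 74.7 CPM. Inflammatory cytokine and NF-kB genes went both ways, 6 higher and 9 lower of 21 (7 and 9 adjusted over the list alone, camera adjusted p = 0.501, adjusted p = 0.883 with an estimated correlation). Il1b, the precursor of interleukin 1 beta, fell from 494 ± 47.4 to 50.7 ± 4.79 CPM from kidney to capsule (log2 fold change -3.29 ± 0.10) and the chemokine Ccl4 had -2.61 ± 0.18. Matrix turnover genes were higher for 14 and lower for 4 of 21 (14 and 4 adjusted over the list alone, 0.0196, adjusted p = 0.251 with an estimated correlation). Mmp9, gelatinase B (ENSMUSG00000017737, chromosome 2, 164940780 to 164955850), stood at 5.05 ± 0.337 and 2346 ± 131 CPM, while the elastase Mmp12 went the other way, 1001 ± 51.2 and 27.4 ± 5.79 CPM (adjusted p = 7.13e-12 and 4.44e-09). Pla2g2d, a secreted phospholipase, stood at 0.625 ± 0.220 and 461 ± 86.3 CPM.

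Markers of other cell types differed between the sites. Fibrillar collagen and interstitial matrix genes were higher in capsule macrophage libraries for 29 and lower for 1 of 32 (29 and 1 adjusted over the list alone, camera adjusted p = 7.46e-12, adjusted p = 0.0831 with an estimated correlation). Adventitial fibroblast genes were higher for 17 and lower for 2 of 20 (17 and 2 adjusted over the list alone, 1.96e-06, adjusted p = 0.0831 with an estimated correlation). Fn1 stood at 14.2 ± 2.57 and 1398 ± 329 CPM and Dcn at 2.20 ± 0.463 and 276 ± 66.4 CPM. Col3a1 had a log2 fold change of 6.39 ± 0.31, and Col1a1 stood at 0.879 ± 0.623 and 96.6 ± 27.3 CPM (6.79 ± 0.41, or 7.41 without kidney replicate 2). The fibroblast genes Scara5 and Igfbp6 had log2 fold changes of 10.27 ± 0.41 and 9.97 ± 0.35 (11.79 and 10.82 without kidney replicate 1). Cilp had 1 count over the kidney libraries, in replicate 3, and 9861 over the capsule libraries, a ratio of 9350 (95% counting interval 1680 to 370000). Of 7 mast cell and basophil genes, 6 were higher in the capsule and none lower (6 adjusted over the list alone, median log2 fold change 5.86, also with 2 members at their bound, or 5.14 without capsule replicate 3; camera adjusted p = 0.0404, adjusted p = 0.572 with an estimated correlation). The mast cell protease Tpsb2, whose reads can be shared with a related tryptase, had 0 counts in kidney libraries and was at least 870-fold higher in the capsule. The mast cell peptidase Cpa3 had a log2 fold change of 5.86 ± 0.98 (5.14 without capsule replicate 3). Tubule genes were higher in kidney macrophage libraries. Of 29 proximal tubule genes, 26 were lower and 1 higher in the capsule (26 and 1 adjusted over the list alone, 2.88e-08, adjusted p = 0.572 with an estimated correlation; none higher without capsule replicate 1 or 2 or any kidney replicate). All 18 loop and distal nephron genes were lower (18 adjusted over the list alone, 1.42e-07, adjusted p = 0.379 with an estimated correlation). The proximal tubule sum was 5341 ± 1400 CPM in kidney and 570 ± 142 CPM in capsule macrophages, and the loop sum 447 ± 91.1 and 13.7 ± 13.1 CPM (exact permutation p = 0.0286 for both). Slc34a1 stood at 440 ± 79.0 and 14.2 ± 17.5 CPM (log2 fold change -4.94 ± 0.71, or -6.32 without capsule replicate 1), Gatm at 709 ± 13.4 and 196 ± 41.2 CPM, Pck1 had -4.05 ± 0.31 and Egf -4.62 ± 0.41. Genes of largest fall included Car12 (-7.96), Kcnj15 (-7.83), Proc (-7.64), Tmem252 (-6.51), Slco4a1 (-6.45), Tfcp2l1 (-6.44), Cyp2j13 (-6.25), a member of a gene family with near-identical copies, and Slc17a3 (-6.24), all at 0.469 CPM or less in capsule macrophages. Without capsule replicate 1 Kcnj15, Tmem252 and Slc17a3 had -8.48, -7.56 and -8.28, and Proc and Tfcp2l1 had no counts left in the capsule group; without capsule replicate 4 Slco4a1 had -7.87. Acta2 did not differ past the threshold (0.41 ± 0.42, adjusted p = 0.427). Pecam1 was lower in the capsule (-0.76 ± 0.28, 0.0371), a call lost without capsule replicate 1 (0.0615) or 4 (0.0942) or kidney replicate 1 (0.0708), 2 (0.0873) or 4 (0.0731).

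The third comparison set aged against young RCAM libraries. Vcam1, a vascular cell adhesion molecule also made by some macrophages (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688), rose from 59.0 ± 5.78 to 271 ± 26.3 CPM (n = 4 each, log2 fold change 2.20 ± 0.10, edgeR adjusted p = 9.75e-06). Gpnmb, a glycoprotein of lipid-laden macrophages (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), rose from 6.21 ± 4.10 to 90.3 ± 29.3 CPM (3.86 ± 0.43, 0.00151). Retnla (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461) fell from 11980 ± 2560 to 4868 ± 729 CPM (-1.30 ± 0.16, 0.0022), and Mgl2, a galactose-binding lectin, from 1747 ± 141 to 814 ± 85.5 CPM (-1.10 ± 0.09, 0.000489). Of 15182 genes tested, 520 were higher and 209 lower in aged libraries, 4.8% of all, and groups did not overlap for 11.7%, where chance gives 2.86%. DESeq2 called 937 higher and 504 lower. Without young replicate 1, 2 or 4 there were 139, 122 and 98 lower genes, without aged replicate 1 or 2 there were 130 and 132, and without aged replicate 4 there were 340 higher and 114 lower. Fibroblast transcripts were highest in aged replicates 3 and 4, and without both 172 genes were higher and 51 lower.

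**Figure D4:**
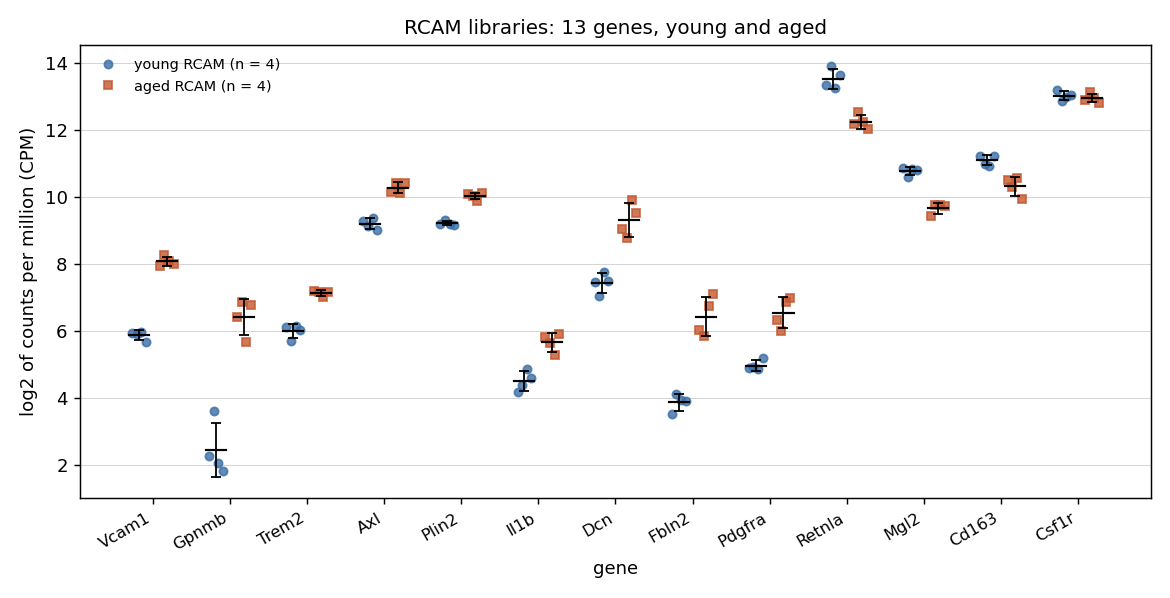
Level of 13 genes in young and aged RCAM libraries, as log2 CPM, with a point per library and a black bar at the mean ± SD of the log2 values. Vcam1 stood at 59.0 CPM in young and 271 CPM in aged libraries and Retnla at 11980 and 4868 CPM, without overlap, while Csf1r overlapped between the groups.

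No gene of the pan-macrophage list passed the threshold, while a minority of the genes in the Lyve1-type and Cx3cr1-type lists did. Of 16 pan-macrophage genes, 0 passed in edgeR (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 by limma-voom and 0 by DESeq2; camera adjusted p = 0.547, adjusted p = 0.904 with an estimated correlation). Their sums were 42600 ± 1080 and 44180 ± 1910 CPM in young and aged libraries (exact permutation p = 0.229). Csf1r (-0.07 ± 0.09, adjusted p = 0.769) and Adgre1 (0.12 ± 0.10, 0.629) did not pass. Of 23 Lyve1-type genes, 8 fell and none rose (9 fell and 2 rose adjusted over the list alone, median log2 fold change -0.20, camera adjusted p = 1.43e-05, adjusted p = 0.458 with an estimated correlation). The number that fell was 5 without young replicate 1, young replicate 2 or aged replicate 2, and 4 without young replicate 4 or without aged replicates 3 and 4 together. Without young replicate 3, 1 gene rose, and 2 did without aged replicate 4. They included Cd163 (2189 ± 233 to 1296 ± 241 CPM, 0.0128) and the chemokine Ccl24 (563 ± 95.8 to 279 ± 64.6 CPM, 0.0102). The list summed to 40190 ± 2430 CPM in young and 26970 ± 3490 CPM in aged libraries (exact permutation p = 0.0286). Lyve1 itself stood at 1489 ± 234 and 861 ± 246 CPM (0.0507, 0.0441 without aged replicate 1). Of 14 Cx3cr1-type genes, 5 rose (11 adjusted over the list alone, median 0.62, camera adjusted p = 4.13e-08, adjusted p = 0.133 with an estimated correlation). They included the lipid sensor Trem2 (64.5 ± 8.39 to 140 ± 7.48 CPM, 0.000492) and the efferocytosis receptor Axl (592 ± 61.8 to 1244 ± 147 CPM, 0.000865). Without aged replicates 3 and 4, 3 rose. Cx3cr1 itself did not pass (0.76 ± 0.21, 0.0752). Of 19 lipid-associated macrophage genes, 9 rose (15 adjusted over the list alone, median 0.48, camera adjusted p = 8.95e-10, adjusted p = 0.049 with an estimated correlation). The lipid droplet protein gene Plin2 rose from 596 ± 29.0 to 1041 ± 67.6 CPM and Cd63 from 129 ± 7.41 to 246 ± 21.6 CPM. Of 22 antioxidant and Nrf2 genes, 5 rose (8 adjusted over the list alone, 0.33, camera adjusted p = 3.93e-06, adjusted p = 0.049 with an estimated correlation), led by the extracellular superoxide dismutase Sod3 (1.74 ± 0.27, 0.00708). Without any 1 library other than aged replicates 3 and 4, 3 antioxidant genes passed, without aged replicate 3, 2 did, and without both 3 and 4, 1 did. Of 11 MHC class II genes, H2-DMb2 fell (1 fell and 1 rose adjusted over the list alone; -0.79 ± 0.16, 0.0233, list 0.684, adjusted p = 0.937 with an estimated correlation), a call lost without young replicate 1 (0.0576), young replicate 2 (0.0632) or aged replicate 2 (0.0586), and without aged replicates 3 and 4 together.

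Activation genes moved in both directions. Of 24 immediate early and dissociation stress genes, 6 rose (16 rose and 1 fell adjusted over the list alone, median log2 fold change 0.53, camera adjusted p = 9.33e-07, adjusted p = 0.237 with an estimated correlation). The nuclear receptor Nr4a1 had 1.44 ± 0.20 (adjusted p = 0.00379). The count was 2 without young replicate 2, young replicate 4, aged replicate 4 or aged replicates 3 and 4 together, 3 without young replicate 3, and 9 without young replicate 1. Of 21 inflammatory cytokine and NF-kB genes, 3 rose (7 rose and 1 fell adjusted over the list alone, median 0.26, camera adjusted p = 0.00163, adjusted p = 0.214 with an estimated correlation). They included Il1b (23 ± 4.86 to 51.5 ± 9.50 CPM, 0.0056) and Tnfaip3 (0.70 ± 0.10, 0.00412). Of 33 interferon-stimulated genes, 3 fell and 1 rose (5 and 1 adjusted over the list alone, median -0.21, camera adjusted p = 8e-05, adjusted p = 0.48 with an estimated correlation). Those that fell included Gbp3 (-0.67 ± 0.09, 0.00276), of a family with similar members, and Iigp1 (-0.75 ± 0.16, 0.0256). The interferon genes that fell numbered 1 without aged replicate 1, 2 or 4 and 2 without young replicate 2 or 3. None rose without young replicate 1, 2 or 4 or aged replicate 2, 3 or 4. Without aged replicates 3 and 4 together, 2 fell and none rose. Iigp1 was lost without young replicate 2 (0.0568), 3 (0.0614) or 4 (0.0625) or aged replicate 1 (0.0725), 2 (0.0631) or 4 (0.0677). Of 25 senescence and secretory phenotype genes, 5 rose (8 adjusted over the list alone, median 0.40, camera adjusted p = 0.000213, adjusted p = 0.133 with an estimated correlation). Among those were Gdf15 (2.48 ± 0.807 to 10.5 ± 4.06 CPM, 0.00618), Igfbp7 (2.01 ± 0.24, 0.00226) and Mmp12 (32.5 ± 22.1 to 187 ± 56.4 CPM, 0.00869). Without young replicate 2, 3 or 4, 3 genes of this list passed, and without aged replicates 3 and 4 together, 2 did. Of 10 kidney injury genes, 3 rose, Vcam1, Igfbp7 and the phosphoprotein Spp1 (2.22 ± 0.37, 0.00902), the last of which is also a lipid-associated gene (3 adjusted over the list alone, median 1.51, camera adjusted p = 1.25e-05, adjusted p = 0.049 with an estimated correlation).

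Fibroblast, matrix and vascular lists were higher as sets in aged RCAM libraries. Of 33 fibrillar collagen and interstitial matrix genes, 17 rose (27 adjusted over the list alone, median log2 fold change 1.5, camera adjusted p = 1.11e-15, adjusted p = 0.214 with an estimated correlation). Of 20 adventitial fibroblast genes, 13 rose (20 adjusted over the list alone, median 1.53, camera adjusted p = 1.92e-14, adjusted p = 0.213 with an estimated correlation). Of 23 matrix turnover genes, 9 rose (14 adjusted over the list alone, median 1.37, camera adjusted p = 3.74e-08, adjusted p = 0.058 with an estimated correlation). The proteoglycan Dcn (ENSMUSG00000019929, chromosome 10, 97479609 to 97518143) rose from 176 ± 34.0 to 664 ± 229 CPM (adjusted p = 0.00246). Fbln2 rose from 14.8 ± 2.48 to 91.6 ± 36.7 CPM (0.00109) and the fibroblast receptor Pdgfra from 31.4 ± 3.73 to 97.2 ± 29.8 CPM (0.00266). Bgn and the membrane metalloproteinase Mmp14 had 2.56 ± 0.32 and 2.42 ± 0.27 (0.00268 and 0.00164). The fibroblast list summed to 1117 ± 31.4 CPM in young libraries and to 1853, 1632, 3172 and 3246 CPM in aged replicates 1 to 4. The matrix list summed to 3869 ± 634 and 5217 ± 1650 CPM (exact permutation p = 0.171) and the matrix turnover list to 5801 ± 675 and 5781 ± 355 CPM (0.971). Without aged replicates 3 and 4, 9 matrix, 3 fibroblast and 4 matrix turnover genes passed, and the medians were 0.71, 0.82 and 0.94. No pericyte gene then passed in edgeR, where 2 had an unadjusted p under 0.05 and limma-voom called 0 and DESeq2 1. The pericyte median was then 2.63. Camera with the preset correlation called the list (adjusted p = 0.00403) and the other 3 (3.04e-10, 1.63e-13 and 1.97e-07). With an estimated correlation none of these lists was called even with all libraries, so the preset calls do not settle the matter. Fibroblast genes past the threshold numbered 8, 5, 6 and 4 without young replicate 1, 2, 3 or 4, and 7 and 6 without aged replicate 3 or 4. Matrix genes numbered 11 without young replicate 2 or 4, and matrix turnover genes 5 without young replicate 2, 3 or 4. Col1a1 (0.93 ± 0.40, 0.265) did not pass. Of 17 endothelial genes, 3 rose (7 adjusted over the list alone, median 1.74, or 2.35 without young replicate 1, 0.97 without aged replicate 3 and 1.01 without aged replicates 3 and 4, camera adjusted p = 5.6e-07, adjusted p = 0.0782 with an estimated correlation), with the angiopoietin receptor Tek at 2.60 ± 0.42 (0.00821), but not Pecam1 (0.48 ± 0.27, 0.427). Of 9 pericyte genes, 2 rose (5 adjusted over the list alone, median 2.09, camera adjusted p = 0.000141, adjusted p = 0.0865 with an estimated correlation). The call of Pdgfrb (2.08 ± 0.47, 0.0324) was lost without young replicate 2 (0.0639), 3 (0.0853) or 4 (0.0797) or aged replicate 3 (0.0776) or 4 (0.0864). The pericyte count was 3 without young replicate 1 and 1 without young replicate 2, 3 or 4 or aged replicate 3 or 4, and the endothelial count 2 without young replicate 1, 2 or 3 or aged replicate 3 or 4. Acta2 stood at 1.21 ± 0.30 (0.0511, 0.0263 without young replicate 1), and Slc34a1 at -0.03 ± 0.48 (0.986), with sign changes among the single libraries left out.

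B-lineage lists were also tested. Of 12 B cell genes, 5 rose (5 rose and 1 fell adjusted over the list alone, median log2 fold change 1.32, camera adjusted p = 5.52e-05, adjusted p = 0.0571 with an estimated correlation). Cd22 was among them (3.09 ± 1.44 to 19.5 ± 4.82 CPM, 0.00276). Of 14 plasma cell genes, 2 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.26, camera adjusted p = 0.0273, adjusted p = 0.182 with an estimated correlation). The gene that fell was the transcription factor Irf4 (-1.13 ± 0.09, 0.000474). Of 5 immunoglobulin segments, 2 rose (3 rose and 1 fell adjusted over the list alone, median 0.77, camera adjusted p = 0.0127, adjusted p = 0.232 with an estimated correlation; 1 fell without aged replicate 2). The whole list, with segments too low to test, summed to 1087 ± 89.4 CPM in young and 1895 ± 424 CPM in aged libraries (exact permutation p = 0.0286). Without young replicates 1 to 4 in turn, 7 members were measured, with medians of 2.78, 2.83, 3.04 and 2.97. Without aged replicate 2 or 4, 6 were measured, with medians of 1.57 and 1.87, and without aged replicates 3 and 4 together the median was 1.42 over 7. Segments without counts in a group were not set to bounds in these fits. Jchain had 12 counts over the young libraries, all in replicate 3, and stood at 104 ± 93.7 CPM in aged libraries (0.000861, lost by limma-voom at 0.195). The B cell count was 3 without young replicate 1, 2 or 3 and 2 without young replicate 4, aged replicate 2, aged replicate 4 or aged replicates 3 and 4 together. The camera call of the plasma cell list was lost without young replicate 3 (0.0767), aged replicate 2 (0.0609) or aged replicate 4 (0.0568). Cxcl13 stood at 15.1 ± 14.5 CPM in young and 271 ± 310 CPM in aged libraries (0.027), a call lost without young replicate 1 (0.0688), 2 (0.0694) or 4 (0.069). Its log2 fold change was 4.16, or 5 without young replicate 3 and 2.93 without aged replicate 1. Other genes of large rise were Pamr1 (3.42, or 2.77 without aged replicate 3), the acute phase gene Saa3 (3.25, 0.0166, lost without young replicate 2 at 0.0525 or 4 at 0.0554), Aebp1 (3.11), Gdf3 (3.09) and the lipocalin Apod (3.04). Other genes of large fall were Gbp2b (-2.01, of the Gbp family), the natriuretic peptide receptor Npr1 (-1.60), Nrap (-1.37, lost without young replicate 4 at 0.0535), Diras2 (-1.22) and Lilra6 (-1.22). Cd2 also fell (-1.25, 0.04), a call lost without young replicate 1, 2 or 4 or aged replicate 1, 2 or 3 at 0.053 to 0.0973. The lysozyme gene Lyz1 fell too (-1.22, 0.0426, lost without any library but young replicate 4 at 0.0584 to 0.102), and its reads can be shared with Lyz2.

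The age effects in capsule tissue and in RCAM libraries were then set side by side; no library is shared between them. Across 13781 genes tested in both, their log2 fold changes had a Pearson r of 0.105 and a Spearman rho of -0.012. Of 13 genes higher in aged capsules and 506 higher in aged RCAM libraries, 7 were in common where independent lists give 0.5 (Fisher's exact p = 1.22e-07). They were Cd79a, Kif1a, Mzb1, Cd22, Jchain, Iglc2 and the long noncoding gene Gm30211. Kif1a and Gm30211 were named after their values were seen. Of 10 and 206 lower genes, Akr1c18 and Acss1 were in common where independent lists give 0.1 (Fisher's exact p = 0.00925). No gene went opposite ways past both thresholds, where independent lists give 0.2 higher and 0.4 lower in capsules. With the capsule calls of the replicate block, 796 higher and 1028 lower, 100 genes were higher in both where independent lists give 29.2 (Fisher's exact p = 1.4e-28). There were 12 lower in both, where they give 15.4 (0.424). Opposite ways went 16 genes higher in capsules (11.9, Fisher's exact p = 0.226) and 19 lower (37.7, Fisher's exact p = 0.000714). Fisher's test takes genes as independent draws, which genes expressed together are not, so these p-values can be too small. Cd79a, Mzb1, Cd22, Jchain and Iglc2, for example, are all B-lineage genes. The block calls also rest on a pairing chosen from these data. The interaction test found 952 of 18856 genes whose age effect differed, 589 more positive and 363 more negative in RCAM libraries, with tissue preparation and possibly the kit differing between the 2 as well. Its fit held no replicate block, although the replicate numbers were taken to pair the capsule libraries. The interaction count was 327 without young capsule replicate 1, 282 without aged capsule replicate 1 and 1594 without aged capsule replicate 3. Without a single RCAM library it was 566, 633, 524 and 491 for young replicates 1 to 4, and 518, 574 and 495 for aged replicates 1, 3 and 4.

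The site sets were followed through both age comparisons. In RCAM libraries the kidney macrophage set had a median log2 fold change of 0.39, with 15 of 198 measured genes higher and 1 lower (camera p = 3.09e-08, p = 0.164 with an estimated correlation). The capsule macrophage set went both ways, with 30 of 200 genes higher and 36 lower, a median of -0.15, a mean of 0.09 and camera pointing downward (p = 0.0493, p = 0.532 with an estimated correlation). Of these genes 19 were in the matrix or fibroblast lists, and 10 of the 19 were higher and none lower. The other 181 had 20 higher and 36 lower, with a median of -0.18 (p = 0.000393, p = 0.29 with an estimated correlation), an alternative added after the data were seen. In capsule tissue the kidney macrophage set had a median of -1.72 (195 genes, p = 5.64e-14, p = 0.236 with an estimated correlation). The capsule macrophage set had one of 0.28 (195 genes, p = 0.000125, p = 0.392 with an estimated correlation). No member of either set passed the threshold over all genes in edgeR. With the replicate block 5 members of the kidney set were higher and 123 lower, and 35 and 3 of the capsule set. At an unadjusted p under 0.05 these were 13 and 122, and 46 and 8, by limma-voom 3 and 109, and 13 and 5, and by DESeq2 10 and 103, and 25 and 6. The capsule set was drawn from libraries with fibroblast transcripts, which were higher in aged RCAM libraries, and the kidney set from libraries with tubule transcripts, which were lower in aged capsules as a group.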

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

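The test against whole capsule tissue and leaving out aged replicates 3 and 4 in the first pattern, and the use of the planned tubule covariate on the second, were chosen after the results were seen.

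Fibroblast and matrix genes were higher in aged RCAM libraries. Against RNA of whole capsule tissue as the cause, the adipocyte list, the most abundant list of capsule tissue, gained 52.4 CPM where the gain of the adventitial fibroblast list (1360 CPM) would need 4170 CPM, a gap beyond the summed SDs of 108 CPM. The gain of the 53 members of the fibroblast and matrix lists ranked with their level in aged capsule tissue (Spearman rho 0.65). Their median gain was 8.17% of that level (quartiles 4.82 to 14.4). A gain in CPM is larger for abundant genes, so a rise made by the RCAM cells could rank the same way. The ranking thus leaves RNA of capsule fibroblasts and expression by these cells as candidates. Age as their cause was not tested. Fibroblast sums in capsule macrophages of unstated age were 1312 to 1948 CPM. Aged RCAM replicates 1 and 2 lay within that range, 3 and 4 above, young ones below. Without aged replicates 3 and 4, 172 genes were higher and 51 lower.

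Oxidative phosphorylation genes were lower in aged capsules, with a median log2 fold change of -1.09. With the proximal tubule list as a covariate the median was -1.36 (camera p = 1.59e-21 with the preset correlation), and the loop and distal nephron list had a camera adjusted p of 0.408. With the brown and beige adipocyte list as a covariate it was -0.61 (camera p = 1.27e-09 with the preset correlation). Neither fit can decide on less tubule RNA or less brown or beige fat RNA as the whole cause. Each had 3 residual degrees of freedom, and tubule sums ran opposite to the other sums among young capsules. Young replicates 1 to 3 had proximal tubule sums of 30250, 17610 and 41690 CPM. Their oxidative phosphorylation sums were 22340, 34280 and 19260 CPM, and their brown fat sums 2176, 4493 and 1181 CPM. Both losses together cannot be told apart from a change in the tissue, since with both covariates the median was 0.46 (quartiles 0.06 to 0.78, camera p = 0.0994 with the preset correlation) with 2 residual degrees of freedom. The mitochondrially encoded genes then had a median of -2.62. Lower expression with age stays open and was not tested.

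Tubule genes were higher in kidney macrophage than in capsule macrophage libraries. Across 47 tubule genes the level in kidney macrophages ranked with that in young capsule tissue (Spearman rho 0.76), with a median of 42.5% of that level (quartiles 22.7 to 99.4). The proximal tubule sum was 10.5 to 12.6 times the loop sum in the kidney macrophage libraries but 38.7 to 49.2 times in young capsules, so the mix of tubule segments differed from that of this tissue. No library of whole kidney was at hand. Tubule RNA carried into the kidney libraries is a candidate explanation, and uptake or expression by the macrophages themselves stays open as untested.

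Other splits of the same libraries were tested in the same way. Only the real split (1) gave as many genes called between macrophage sites (8701, all 23 Lyve1-type genes among them, at most 0 in the other 34 of 35 splits). The same held for age in RCAM libraries (729, at most 0) and for the interaction, fitted without the replicate block (952, at most 68 in 100 drawn of 700 splits). The other splits mix the groups, so a true difference adds to their spread and lowers their counts. Replicates may also be technical, so these splits cannot exclude chance differences between animals. Even among the splits, chance cannot be excluded for the number of lists camera called between sites (20, other splits up to 20, 2 of 35 as many), a count that tests no single list, for that number in RCAM libraries (23, up to 28, 4 of 35) or for the absolute r between the age effects (0.105, up to 0.135, 5 of 35). Nor can it for the site sets in RCAM libraries by camera with the preset correlation, with p = 3.09e-08 and down to 5.69e-23 for the kidney set (8 of 35) and p = 0.0493 and down to 1.08e-08 for the capsule set (14 of 35). The 10 splits of the capsule libraries are too few for a share under 0.05, with 39 genes for the real split and at most 0 for the others (1 of 10), 29 lists and up to 37 (3 of 10). By camera with the preset correlation they gave p = 0.000125 and down to 1.03e-09 for the capsule macrophage set (5 of 10) and p = 5.64e-14 and down to 1.14e-21 for the kidney macrophage set (3 of 10). Of the splits that part all 3 capsule pairs, the real one called 39 genes, or 2196 with the replicate block, and the 3 others, which each exchange 1 pair, called 0 without and 0 with the block.

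Of 216 groups of 4 libraries, 19 held a library far from the other 3 by Dixon's test, which chance alone gives in about 1 in 20 groups. In kidney macrophages these were Cilp in replicate 3 (0.0284 CPM, others 0), Igfbp6 in replicate 1 (0.099, others 0.0193 to 0.0284) and Col3a1 in replicate 4 (1.14, others 2.61 to 2.73). In capsule macrophages they were all in replicate 1: Proc (0.304 CPM, others 0), Tfcp2l1 (0.83, others 0), Slc17a3 (1.5, others 0 to 0.238), Slc34a1 (40.3, others 3.71 to 6.93), the proximal tubule sum (782, others 487 to 519) and the loop and distal nephron sum (33.1, others 4.93 to 9.39). In young RCAM libraries they were Jchain in replicate 3 (0.227 CPM, others 0), Gpnmb and Plin2 in replicate 2 (12.3, others 3.52 to 4.81, and 639, others 576 to 586) and Pdgfra in replicate 4 (36.9, others 28.9 to 30.2). In aged RCAM libraries they were Cxcl13, Mgl2 and the adipocyte sum in replicate 1 (736 CPM, others 106 to 131; 687, others 840 to 869; 308, others 419 to 438), Trem2 and Tek in replicate 3 (129, others 143 to 145, and 14.6, others 5.31 to 6.5) and Cd63 in replicate 4 (214, others 253 to 260).

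The age effect differed between RCAM libraries and capsule tissue for 952 genes by the interaction test and for 32 of 87 named genes. As the log2 fold change in RCAM libraries minus that in capsule tissue, the values were -3.95 for Ighm (adjusted p = 1.02e-05), 1.5 for Acss1 (0.00328), -2.66 for Diras2 (0.0071), 2.08 for Sod3 (0.0138) and 2.08 for Igfbp7 (0.014). At adjusted p values of 0.0146 to 0.0454, single named genes more positive in RCAM libraries were Mmp14 1.99, Aebp1 2.64, Fbln2 2.15, Pdgfra 1.65, Bgn 2.12, Dcn 1.7, Pamr1 2.81, Tek 2.3, Apod 2.16 and Spp1 3.93. So were Ndufs6 (1.28), mt-Co1 (1.32), Cox8b (3.55), Cox7a1 (2.44), Car14 (2.49), Fabp3 (5.18), Cd63 (1.25) and Axl (0.95). More negative there were H2-Q6 (-1.87), H2-Q4 (-1.01), H2-DMb2 (-1.12), C4b (-1.28), Gbp3 (-1.03), Iigp1 (-1.6), Ccl5 (-2.22), Cd2 (-2.01) and Npr1 (-1.65).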

How the results depend on the processing

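Leaving out the adrenal and the fibroblast libraries, 1 of the 2 scalings below, the site sets without fibroblast and matrix genes and the test within capsule pairs were chosen after the results were seen; all the other alternatives were planned. The cause was not tested for any change below, except that fewer libraries or genes enter some fits. In aged capsules 25 genes were higher and 14 lower. The counts were 754 and 1122 by the DESeq2 Wald test, 580 and 953 by limma-voom, 403 and 692 without the low-count filter, 2293 and 804 with all 22 libraries in 1 fit, 1 and 0 at an adjusted p under 0.01, 4 and 4 with immunoglobulin, mitochondrial and haemoglobin genes removed, 29 and 22 with them out of the scaling alone (chosen after), 488 and 291 with the proximal tubule covariate, and 176 and 311 without the adrenal libraries. With the replicate block, which the pairing check favoured in capsules, they were 943 and 1253; beyond the values printed beside the capsule results, the block changed no other call of a gene or list named there. Leaving out 1 library gave 0 to 93 higher and 0 to 324 lower, and 13 to 26 lists higher and 7 to 9 lower. Lists called numbered 22 higher and 7 lower, 0 and 0 with an estimated correlation, and 3 and 0 by fry. Between macrophage sites, 1885 and 2443 genes passed at an absolute log2 fold change of at least 1, and lists numbered 1 and 0 with an estimated correlation and 29 and 11 by fry; leaving out 1 library gave 3869 to 4238 and 3876 to 4582 genes, and 16 to 18 and 4 to 5 lists. In RCAM libraries, genes numbered 937 and 504 by the Wald test and 176 and 36 at an adjusted p under 0.01, with 114 lower in 1 fit of all libraries and 34 lower at an absolute log2 fold change of at least 1. Without aged replicates 3 and 4 they numbered 172 and 51, and leaving out 1 library gave 340 to 497 and 98 to 153. Lists there numbered 3 and 0 with an estimated correlation, 0 lower by fry, and 18 to 25 and 2 to 5 leaving out 1 library. The interaction called 1822 genes by limma-voom, 2355 by the Wald test and 282 to 1594 leaving out 1 library. The r of the age effects was 0.071 to 0.144 leaving out 1 library, with a Spearman rho of -0.012.

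For site and RCAM libraries the replicate numbers gave no sign of pairing (correlations of 0.008, 0.105, -0.054 and 0.083 for replicates 1 to 4 between sites, and -0.236, -0.054, -0.154 and -0.166 in RCAM libraries). With the replicate block 3954 genes were higher and 4267 lower between sites, and 280 and 56 in RCAM libraries. The capsule macrophage set in RCAM libraries had a median of -0.05 with 50 genes (p = 0.547), -0.01 with all genes past the threshold (p = 0.856) and -0.15 with an estimated correlation (p = 0.532), where the kidney set had 0.39 (p = 0.164). Without fibroblast and matrix genes the capsule set had a median of -0.18 in RCAM libraries and 0.33 in capsule tissue, with the same direction and call. In capsule tissue with an estimated correlation the 2 sets had 0.28 (p = 0.392) and -1.72 (p = 0.236). None of the genes whose sign changed was past the threshold: Cx3cr1 in capsules (0.67 with the tubule covariate, -0.49 to 0.18 leaving out 1 library), Lyve1 in capsules (-0.01 without the adrenal libraries), Col1a1 in RCAM libraries (-0.04 without aged replicates 3 and 4) and Slc34a1 in RCAM libraries (0.01 with the block, -0.26 to 0.44 leaving out 1 library). Over the alternatives of all named genes, direction and side of the threshold stayed the same in 1153 cases for capsules (311 calls gained, 111 lost, 3 of the other sign), 1514 for sites (14 lost) and 1796 for RCAM libraries (39 gained, 196 lost, 5 of the other sign). Capsule libraries had the lowest depth, from 20.6 M counts (1e6).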

Other observations

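The lists and their tests were planned, while the choice of these 2 lists and leaving out aged replicates 3 and 4 together came after the results were seen. Platelet genes were higher in capsule than in kidney macrophage libraries. All 8 measured passed (8 adjusted over the list alone, median log2 fold change 4.12, camera adjusted p = 0.00189, adjusted p = 0.52 with an estimated correlation). The chemokine gene Pf4, which is also in the Lyve1-type macrophage list, stood at 40.0 ± 4.38 CPM in kidney and 989 ± 50.2 CPM in capsule macrophages (log2 fold change 4.63 ± 0.10, adjusted p = 6.29e-10). Ppbp, a chemokine of platelet granules, stood at 0.625 ± 0.166 and 15.3 ± 10.6 CPM (5.16e-05), and the integrin Itga2b at 1.07 ± 0.390 and 16.4 ± 11.9 CPM (0.000227).

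Basement membrane genes were higher in aged than in young RCAM libraries, next to the fibroblast and vascular genes that were also higher there. Of 16 measured, 6 rose and 1 fell (9 and 1 adjusted over the list alone, median log2 fold change 1.46, camera adjusted p = 1.24e-05, adjusted p = 0.196 with an estimated correlation). The collagen gene Col4a1 rose from 20.1 ± 6.84 to 72.4 ± 18.1 CPM (adjusted p = 0.00382), the laminin chain Lama4 from 4.49 ± 1.42 to 22.8 ± 10.7 CPM (0.0056), Sparcl1 from 6.50 ± 2.77 to 38.5 ± 18.0 CPM (0.0056) and the linker Nid1 from 34.3 ± 6.74 to 106 ± 45.2 CPM (0.00997). Without aged replicate 3 or 4, 4 members rose, as without both, where the median was 0.65 (camera adjusted p = 0.00455 with the preset correlation). None fell without young replicate 3 or 4 or aged replicate 1, 2 or 4.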
